A study of Homo sapiens with 25 samples.

How the data were processed

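Total RNA was profiled on 25 Affymetrix arrays of 2 designs, 15 of the U95A design and 10 of the U133A design. On each array short oligonucleotide probes are gathered into probe sets, and every probe set reports the abundance of a transcript. The U133A arrays covered 5 groups of MCF-7 cells with 2 arrays each: cells infected with adenovirus for green fluorescent protein (GFP), c-Myb, A-Myb, and 2 chimeras with exchanged domains. The U95A arrays covered MCF-7 cells left uninfected or infected with the GFP, c-Myb or A-Myb virus, with 2 arrays each. A further 7 U95A arrays came from primary lung cells, with 1 array per group. Infected cells were collected after 16 hours, and about 5 µg of RNA was used per array, per the labels.

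Each value is a signal intensity on a linear scale, made by the authors with Affymetrix MAS software, per the labels; the version is not given in the sources used here. The deposited intensities had been scaled per array, since the mean after trimming 2% of each tail lay between 500.06 and 500.88 on all 25 arrays. For this reason the values were used as deposited, without further scaling. No detection calls were used here. On the 7 lung arrays 25 probe sets had no value and were left out.

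Probe sets were named through a platform annotation table. Of 22283 U133A probe sets, 19071 carried 1 gene symbol, 1043 several and 2169 none, and 68 were control probe sets. Of 12625 U95A probe sets, 10961 carried 1 symbol, 545 several and 1119 none, and 67 were controls. Control probe sets were left out of all tests, as were XIST and Y-linked genes, and no gene was named from a probe set with several symbols. The symbols covered 11939 genes on U133A and 8213 on U95A.

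Values were floored at the 20th percentile of all values in a fit and converted to log2. The floor was a signal of 45.7 on U133A and 69.5 on U95A in the fits of MCF-7 cells. The lung comparisons took their percentiles from all 15 U95A arrays, with a floor of 54.5 and a 40th percentile of 150.2, so a difference from a signal below that floor is a bound. A probe set was kept if at least 2 arrays lay above the 40th percentile, a signal of 134.7 on U133A and 175.2 on U95A. This left 17327 probe sets of 10078 genes on U133A and 11386 probe sets of 7668 genes on U95A. Because of the floor, the change of a dim gene is understated. Probe sets of a gene were tested separately, and gene lists used the brightest probe set of each gene.

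Group means were fitted across all MCF-7 arrays of a design with limma 3.58.1 in R 4.3.3, with a mean-variance trend in the empirical Bayes step. The residual degrees of freedom were 5 on U133A and 4 on U95A. P-values were two-sided and adjusted by the Benjamini-Hochberg method within each comparison, and a probe set passed at an adjusted p under 0.05. The comparisons were each Myb protein against GFP, A-Myb against c-Myb, the 4 single domain exchanges, and 3 combined contrasts over the 4 Myb proteins. The DNA binding domain effect was the mean of the proteins with the A-Myb DNA binding domain minus the mean of those with the c-Myb domain. The transactivation domain effect was defined in the same way, and the interaction was the difference between the effects of an exchange in each background. On U95A, GFP was also compared with uninfected cells. Errors after ± are standard errors of the fit for log2 changes and SDs over 2 arrays for signals.

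Before the data were examined, 22 gene lists were written: the Myb family, reported Myb targets, G1/S genes under E2F, G2/M genes bound by Myb-MuvB complexes, replication histones, ribosomal proteins, estrogen response, steroid and xenobiotic metabolism, cholesterol synthesis, endoplasmic reticulum stress and amino acid genes, heat shock, hypoxia and glycolysis, immediate early genes, NF-kB and inflammatory genes, interferon response, p53 targets, apoptosis regulators, and markers of haematopoietic, epithelial, fibroblast, endothelial and differentiated airway cells. A list of metallothionein genes was added after the calls had been seen. Lists with at least 5 measured genes were tested with camera, which compares a list with all other genes, at a preset inter-gene correlation of 0.01; p-values were adjusted over the 21 lists tested in a comparison. Camera was repeated with a correlation estimated from the residuals, and fry tested whether the genes of a list moved one way on balance. The count adjusted over the list alone uses the genes of a list as its only family of tests.

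Genes were named by a rule written before the data were examined. MYB, MYBL1 and MYBL2 came first, then the 12 rising and 12 falling genes with the largest log2 change among those that passed. Each of these genes was represented by its brightest probe set that passed. Where none passed, the 5 with the smallest p in each direction were taken. From each list came up to 4 members that passed, or otherwise up to 2 as values. In the lung cells the 10 largest differences in each direction were taken, among probe sets above the 40th percentile on the higher array, together with the genes named for MCF-7 cells. Members of the G2/M list in the lung cells, further members of the metallothionein list and genes raised by all 4 proteins were named after their values had been seen, and the G2/M genes measured in all 3 comparisons of a lung cell type were compared after that.

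The lung comparisons have 1 array per group and were given as differences of log2 signal without a test. The median of a list was set against 10000 random lists of the same size, drawn within 20 bins of mean expression. Shares of genes carry 95% Wilson intervals, which treat genes as independent although they are not. Overlaps between comparisons that share the GFP arrays were set against 50 simulations of unchanged groups.

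The fits were tested on simulated data, with 20 simulations of 200 changed probe sets placed on the arrays' own spread. For c-Myb against GFP on U133A, 18.9% of 2-fold and 46.2% of 4-fold changes were recovered among a median of 16288.5 probe sets tested, and 7.41% of calls were false. For the transactivation domain effect 37.5% and 70.0% were recovered, with 6.88% of calls false. These shares apply to the simulated data. Probe sets of a real array can deviate together, so the false share of the real calls was not measured. On U95A, c-Myb against GFP recovered 0% of 2-fold and 1.17% of 4-fold changes among a median of 10474.5 probe sets, so few changes were detectable there. A list of 30 genes moved by 0.5 on the log2 scale was found in both U133A comparisons and not on U95A, where its adjusted p was 0.61 with limma's camera. That step used 4000 genes. Genes of a real list can move together, so it does not measure how often a real shift would be found.

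The alternatives tried were quantile normalization, scaling of every array to a common median, a floor at the 5th percentile, no filter or a filter at the 60th percentile, empirical Bayes without a trend, only the arrays of the groups compared, the replicate number as a block, an adjusted p under 0.10, and leaving out each array in turn. Without an array, its group rests on a lone array that is assumed to vary like the other groups. Added after the data had been seen were fits without the U95A arrays of narrow signal range, with signal range as a block, and without CHA array 2. The list tests under other scalings and without each array were also added then. Summaries and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.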

Results

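The series addressed which part of a Myb transcription factor determines the genes it regulates. c-Myb and A-Myb are related proteins with similar DNA binding domains near the N-terminus and more divergent transactivation domains. MCF-7, a human breast cancer cell line that expresses the estrogen receptor, was infected with recombinant adenovirus for GFP alone, c-Myb, A-Myb or a chimera. The chimera AHC joined the DNA binding domain of A-Myb to the transactivation domain of c-Myb, and CHA carried the reverse combination. These 5 groups were profiled on U133A arrays with 2 arrays each. MCF-7 cells left uninfected or infected with GFP, c-Myb or A-Myb virus were profiled on U95A arrays with 2 arrays each. Primary human small airway epithelial cells and lung fibroblasts were profiled on U95A with 1 array per group, so the lung comparisons are without replicates. RNA was taken 16 hours after infection.

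The signal intensities were those deposited by the authors, scaled per array and converted here to log2. Replicate U133A arrays correlated across probe sets with Pearson's r between 0.848 for CHA and 0.924 for c-Myb. Replicate U95A arrays of MCF-7 cells correlated at 0.939 for c-Myb, but at 0.705 for uninfected cells, 0.579 for A-Myb and 0.535 for GFP. Probe sets are not independent replicates. The labels do not state that replicate arrays came from separate cultures, so p-values measure only the spread between these samples, which may be technical. For all comparisons the number of arrays limits the precision. Labels of the U95A arrays name chicken Myb proteins, whereas those of the U133A arrays give no species. A signal of human MYB or MYBL1 therefore need not report the introduced protein.

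c-Myb raised keratin 16 and the short-chain dehydrogenase DHRS2 more than any other named gene in MCF-7 cells. KRT16, a keratin of stressed and hyperproliferative epithelium, rose from a signal of 115.1 ± 107.1 with GFP to 4539 ± 918.1 with c-Myb (SD, n = 2), a log2 change of 5.59 ± 0.44. DHRS2 rose by 4.22 ± 0.19, from 386.0 ± 52.8 to 7200 ± 1220 (SD, n = 2). A second DHRS2 probe set that passed rose more, by 5.34 with c-Myb, 3.66 with A-Myb, 4.18 with AHC and 3.53 with CHA. The stress-inducible GADD45B rose by 3.30, the zinc finger gene ZNF318 by 3.11, the trafficking and kinetochore gene TRAPPC12 by 3.08 and the protein phosphatase PPM1E by 2.91. ACAA2 of mitochondrial fatty acid oxidation rose by 2.82, the RNA-binding protein gene KHDRBS3 by 2.82, the adaptor SHB by 2.80, the transcription factor SOX4 by 2.75, MT1HL1 by 2.70 and the interleukin 4 receptor IL4R by 2.67. Among the genes that fell were HLA-G at -1.51, ABITRAM at -1.45, the semaphorin SEMA3C at -1.32, SERINC3 at -1.27, the chromatin remodeller CHD4 at -1.20 and SFXN1 at -1.18. ZNF287 (-3.21), the glutamate transporter SLC1A2 (-3.09), caveolin CAV3 (-2.94), MC2R (-2.89) and NTRK3 (-2.37) also fell, but their signals with GFP were only 388.3 to 502.7, and ZNF287 and SLC1A2 lay below the floor of 45.7 on both c-Myb arrays and MC2R on 1, so the floor sets part of these changes. Each gene is given from a probe set that passed, and GADD45B, ACAA2, SOX4, ZNF287 and NTRK3 each had another probe set of the opposite sign. Human MYB (-0.10) and MYBL2 (-0.49) did not pass the test.

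In the test of c-Myb against GFP, 158 of 17327 probe sets passed, 138 up and 20 down, covering 121 and 17 genes; 122 changed at least 2-fold. The unadjusted p was under 0.05 for 1933, against 866.35 expected by chance. The count was 54 without c-Myb array 1, 34 without c-Myb array 2 and 58 without GFP array 2, and of the 24 genes named by size DHRS2, KRT16 and MT1HL1 passed without each of the 4 arrays. It was 2 without a trend in the spread, 46 with no filter, and 300 (295 up and 5 down, or 98.3% against 87.3% up) with every array scaled to a common median, which moved the median change from -0.09 to 0.15.

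Of 37 measured genes of the estrogen response, 6 rose with c-Myb and 31 did not pass, and 11 rose and 3 fell adjusted over the list alone. SERPINA3 rose by 1.85, IL17RB by 1.60, the growth factor binding protein IGFBP4 by 1.58 and FHL2 by 1.54. The list had a camera adjusted p of 0.000333, and an adjusted p = 0.193 with an estimated correlation. Of 29 epithelial markers 3 rose and none fell: KRT16, the mucin MUC1 (1.07) and the desmosome gene DSP (0.81), with a camera adjusted p of 0.00583 and an adjusted p = 0.159 with an estimated correlation. No replication histone passed among 12; H2AC17 was at 2.14 and H1-3 at 1.52, and the list's adjusted p was 0.00152, or adjusted p = 0.193 with an estimated correlation. These list calls held without each of the 4 arrays.

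The hypoxia and glycolysis list (28 genes, with hexokinase HK2 raised by 2.06) had an adjusted p of 0.00583, or 0.0596 without c-Myb array 1 and adjusted p = 0.159 with an estimated correlation. Heat shock genes (20 genes, HSPB1 raised by 1.06) had an adjusted p of 0.0122, or 0.104 without GFP array 2, 0.0835 without c-Myb array 1, and adjusted p = 0.159 with an estimated correlation. The immediate early genes (23, none passing; CCN1 1.96, DUSP1 -1.08) had an adjusted p of 0.0387, or 0.0602 after quantile normalization, 0.163 without GFP array 1, 0.0596 and 0.0818 without c-Myb arrays 1 and 2, and adjusted p = 0.193 with an estimated correlation. The ribosomal proteins (31, none passing, median -0.22) were lower at an adjusted p of 0.0295, or adjusted p = 0.734 with an estimated correlation; this was 0.342 after quantile normalization, 0.930 with an upward direction after scaling to a common median, 0.477 without GFP array 1 and 0.816 without c-Myb array 2.

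The remaining lists did not pass with c-Myb. Reported Myb targets, drawn largely from haematopoietic cells, had a median of -0.24 and no member that passed among 32 (CSF1R -1.92, MPO -1.68). Medians were -0.17 for 36 G2/M genes (BUB1B -0.99, HMMR -0.86), 0.06 for 38 G1/S genes (CDC25A 0.90, CDC45 -0.90), -0.29 for 25 p53 targets (AEN 1.49) and -0.13 for 21 inflammatory genes (IL1B -1.84). Cholesterol synthesis (22 genes) had a median of -0.03 and a mean of 0.03, although INSIG1 rose by 1.27 on 1 of its probe sets, with another of the opposite sign. Steroid and xenobiotic metabolism (19 genes) had a median of -0.13 and a mean of 0.04, with GSTM3 up by 1.35 and the quinone reductase NQO1 by 1.12. Among 30 genes of endoplasmic reticulum stress and amino acid supply (median -0.08) the chaperone DNAJB9 rose by 1.30 and the transporter SLC7A5 by 1.01. The interferon list (30 genes, median -0.24) held 1 gene that rose, the exonuclease ISG20 at 2.06. Apoptosis regulators had a median of 0.02 and a mean of -0.12 over 25 genes. Markers of other cell types were at -0.23 for 38 haematopoietic, -0.07 for 27 fibroblast, -1.03 for 5 endothelial and -0.33 for 9 differentiated airway genes, and none of these markers passed.

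A-Myb raised many of the genes named for c-Myb. KRT16 rose by 4.56 ± 0.44, PPM1E by 3.37 ± 0.43, the carbonic anhydrase-related gene CA8 by 3.31 ± 0.42 and the homeobox gene LHX6 by 3.22 ± 0.50. MT1X, a metallothionein that binds zinc and copper, rose by 3.21, the chemokine receptor CXCR4 by 3.10, DHRS2 by 3.08, IL4R by 3.04 and the Cdc42 effector CDC42EP1 by 2.97. ZNF318 rose by 2.82, TRAPPC12 by 2.77 and KHDRBS3 by 2.75. Only 2 named genes fell with A-Myb against GFP: kynureninase KYNU of tryptophan breakdown at -1.99 and the recombination gene RAD51C at -0.89. MYB (-0.26), MYBL1 (-0.40) and MYBL2 (-0.04) did not pass.

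For A-Myb against GFP 125 probe sets passed, 121 up and 4 down, of which 97 changed at least 2-fold, and 1636 had an unadjusted p under 0.05. The count was 68 and 40 without A-Myb arrays 1 and 2 and 53 without GFP array 2; it was 0 without a trend in the spread, where 1458 had an unadjusted p under 0.05 in limma, 46 with no filter and 26 with only the arrays of these groups. CA8, DHRS2, KRT16, KYNU, MT1X and PPM1E passed without each of the 4 arrays. Of 37 estrogen response genes 6 rose, among them FHL2 (2.19), GREB1 (2.02), IL17RB (1.95) and SERPINA3 (1.40), and 11 rose and 1 fell adjusted over the list alone. GREB1 had another probe set of the opposite sign. The camera adjusted p was 0.000275, and an adjusted p = 0.225 with an estimated correlation. In the G1/S list the replication clamp PCNA (1.37) and the ribonucleotide reductase subunit RRM2 (0.96) rose among 38 genes, and 4 rose adjusted over the list alone, with an adjusted p of 0.00182 and an adjusted p = 0.225 with an estimated correlation. The estrogen and G1/S calls held without each array. For G2/M genes CKS2 alone rose (0.99), and the adjusted p of 0.0120 became 0.218 without GFP array 1, 0.130 without A-Myb array 2, 0.0950 after quantile normalization and adjusted p = 0.317 with an estimated correlation. Heat shock genes (none passing) and hypoxia genes (BHLHE40 1.15) each had a median of 0.17, an adjusted p of 0.0120 and an adjusted p = 0.225 with an estimated correlation. For heat shock the adjusted p was 0.0674 without GFP array 2 and 0.0807 without A-Myb array 2; for hypoxia it was 0.0674 without GFP array 2 and 0.0702 without A-Myb array 1.

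With AHC KRT16 rose by 4.07 ± 0.44, LHX6 by 4.02 ± 0.50 and TM4SF1, a tetraspanin-like membrane protein, by 3.80 ± 0.47. PLCXD1 rose by 3.68, TRAPPC12 by 3.49, DHRS2 by 3.48, ZNF318 by 3.39, IL4R by 3.28, PPM1E by 3.13, CA8 by 3.02 and ISG20 by 2.86. Genes that fell included KYNU at -2.56 ± 0.33, the transcription factors ELF1 at -2.34 and BATF at -1.70, the sorting nexin SNX17 at -2.81, the guidance receptor ROBO1 at -2.43, RBMS1 at -2.10, the hyaluronan receptor HMMR at -1.66 and SYT1 at -1.59. ZNF287 (-3.21), GABBR2 (-2.89) and NRF1 (-2.60) fell to means of 24.1, 58.4 and 44.5; ZNF287 lay below the floor on both AHC arrays and NRF1 on 1, so the floor sets part of these changes. GABBR2 and NRF1 each had another probe set of the opposite sign.

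With AHC against GFP 272 probe sets passed, 213 up and 59 down, and 2147 had an unadjusted p under 0.05. Scaling to a common median gave 193 up and 22 down, or 89.8% against 78.3% up. The count was 132 and 98 without AHC arrays 1 and 2, 176 and 129 without GFP arrays 1 and 2, 6 without a trend in the spread, 82 with no filter and 148 with only the arrays of these groups. Estrogen response genes split, with 7 up and 1 down among 37: IL17RB rose by 2.55, IGFBP4 by 1.93 and GREB1 by 1.64, with another GREB1 probe set of the opposite sign. Their median was -0.09 and their mean 0.17, and camera gave an upward adjusted p of 0.0262, or 0.154 without GFP array 2, 0.276 without AHC array 1, 0.0520 after quantile normalization and adjusted p = 0.737 with an estimated correlation. Hypoxia and glycolysis genes HK2 (2.42), BHLHE40 (1.42) and NDRG1 (1.15) rose among 28, with an adjusted p of 0.0109, or 0.111 without AHC array 1 and adjusted p = 0.272 with an estimated correlation. In steroid and xenobiotic metabolism GSTM3 rose by 1.26, while the estrogen-hydroxylating CYP1B1 (-1.38), AKR1C2 (-1.14) and AKR1C1 (-0.90) fell, and the list of 19 did not pass. The immediate early genes KLF10 (1.55) and DUSP5 (1.36) rose among 23, with an adjusted p of 0.0142, or 0.0686 without GFP array 1, 0.276 without AHC array 1 and adjusted p = 0.272 with an estimated correlation. G2/M genes were lower (median -0.36), although CDC25B rose (0.74), with an adjusted p of 0.0125, or 0.155 without GFP array 2, 0.0685 without AHC array 1 and adjusted p = 0.452 with an estimated correlation. The only reported Myb target that rose was CXCR4 (2.07). The secretory protein gene AGR2 fell (-0.91), whereas MUC1 rose (1.19).

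CHA raised KRT16 by 4.61 ± 0.44 and PPM1E by 4.01 ± 0.43. INTS7 rose by 3.30, the ciliary gene ZMYND10 by 3.29, CA8 by 3.02, ZNF318 by 2.87, CXCR4 by 2.78, LHX6 by 2.76, CDC42EP1 by 2.63, MT1X by 2.53 and CXXC1 by 2.31. ZNF318 had another probe set of the opposite sign. GOLPH3L (-3.04), the adhesion receptor ADGRG1 (-2.55) and RHBDF1 (-1.50) fell. PCNA (1.42) and RRM2 (1.07) rose in the G1/S list, whose adjusted p was 0.00353, or 0.0843 without CHA array 2 and adjusted p = 0.568 with an estimated correlation. In all 69 probe sets passed, 66 up and 3 down, and 2095 had an unadjusted p under 0.05. CHA array 2 correlated least with the other U133A arrays: without it 21 passed, 17 up and 4 down, and 36 passed without GFP array 2. Without CHA array 1 the balance of directions turned, with 183 passing, 67 up and 116 down, or 36.6% up against 95.7%. The count was 36 with scaling to a common median, 0 without a trend in the spread, where limma gave 1806 with an unadjusted p under 0.05, and 5 with only the arrays of these groups.

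Metallothionein genes, which encode small metal-binding proteins induced by zinc and other metals, rose with each of the 4 proteins. Of 9 measured genes, 5 rose with c-Myb, 6 with A-Myb, 6 with AHC and 5 with CHA, and none fell. Their median changes were 2.05 with A-Myb, 2.11 with AHC and 1.58 with CHA. These values use 1 probe set per gene. MT1E and MT1F each had 1 probe set that passed with each of the 4 proteins (1.45 to 1.95 and 1.78 to 2.11). Each also had another that passed with none (-0.54 to -0.12 and 0.05 to 0.71). MT2A rose from 5514 ± 327.3 with GFP to 15840 ± 4231 with c-Myb and 23300 ± 5097 with A-Myb (SD, n = 2). MT1X rose by 2.21 with c-Myb and 2.50 with AHC. This list was written after the calls had been seen, so its counts are not independent evidence. Camera with an estimated correlation gave p = 0.0174, 0.00678, 0.0143 and 0.0182, which unlike those of the other lists are not adjusted for the number of lists; the direction held under both other scalings. Each metallothionein probe set that passed is marked in its identifier as one that may share sequence with other genes of the family, so the rise cannot be assigned to single members. The list also lay higher with A-Myb than with c-Myb (median 0.47, unadjusted camera p 0.000652, or 0.146 with an estimated correlation, 0.236 without A-Myb array 2 and 0.0523 without c-Myb array 1). With the A-Myb DNA binding domain its median was 0.43 (p 0.000403, or 0.134 with an estimated correlation and 0.0573 without AHC array 2). CHA lay below A-Myb (median -0.27, p 0.00121, or 0.163 with an estimated correlation, 0.302 without A-Myb array 2 and 0.156 without CHA array 1). No member passed in these 3 comparisons.

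**Figure D1:**
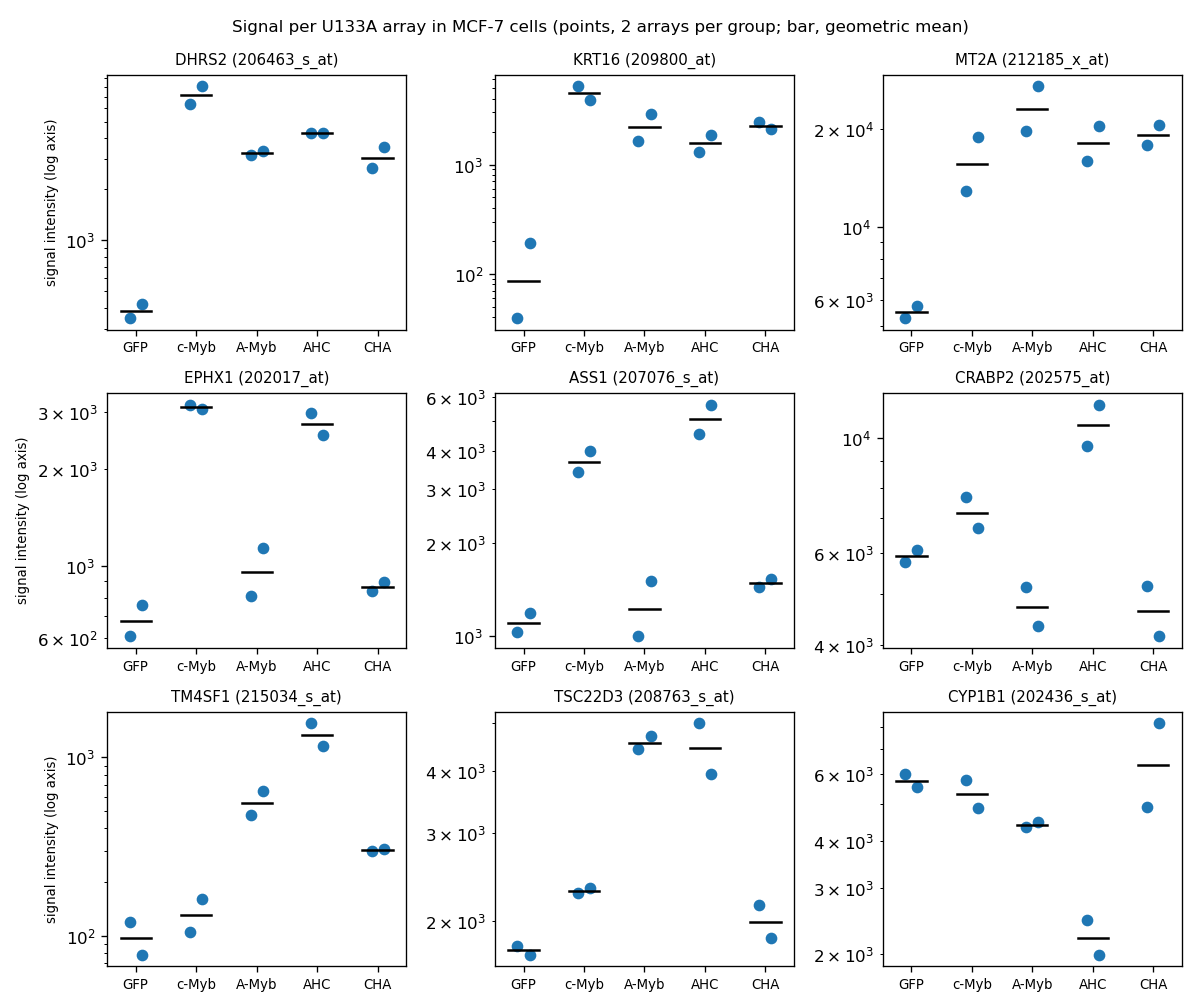
Signal intensity on a log axis of selected genes in MCF-7 cells on U133A arrays, by virus. Each point is an array and the line is the geometric mean of 2 arrays; EPHX1 averages 3125 with c-Myb and 2772 with AHC but 973.4 with A-Myb and 865.4 with CHA, while KRT16 is above GFP with each Myb protein.

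Calls of the 4 proteins overlapped. In all 38 probe sets, of 35 genes, were raised by each of the 4, and none was lowered by each. Besides KRT16, DHRS2, PPM1E, LHX6, ZNF318 and CA8 they included the transporter ABCC3 (1.85 to 2.09), the matrix protein TGFBI (1.78 to 2.18), catenin-like CTNNAL1 (1.56 to 1.96), the endothelin-converting enzyme ECE1 (1.33 to 1.95), the chaperone HYOU1 (1.02 to 1.31) and geminin GMNN (1.05 to 1.24). Another 136 were raised by exactly 1 protein, 65 by 2 and 40 by 3. Between 47 and 103 probe sets were raised by both proteins of a pair. Independent lists of the same sizes would share 0.461 to 1.70 (n1 × n2 / N). Simulations of unchanged groups against the same GFP arrays gave a mean of at most 0.02 for any pair. Log2 changes of pairs correlated across probe sets at r = 0.538 to 0.654. Unchanged groups gave means of at most 0.502 over the 50 simulations. Covariances were 0.304 to 0.350, against a mean of 0.192 in each pair's simulations. The simulations drew each probe set independently, whereas probe sets of a real array can deviate together. The 2 GFP arrays were too few to split, so part of the excess may come from the shared controls.

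Few genes passed in the direct comparison of A-Myb with c-Myb. In simulated data c-Myb against GFP, with as many arrays, recovered 18.9% of 2-fold changes. The count thus does not show that the proteins differ in few genes. EPHX1, the microsomal epoxide hydrolase, was lower with A-Myb by -1.70 ± 0.22, and argininosuccinate synthase ASS1 by -1.59 ± 0.21. The fatty acid binding protein FABP5 (-1.59), the cell cycle checkpoint protein 14-3-3 sigma gene SFN (-1.21) and DHRS2 (-1.14) were also lower, and the glucocorticoid-induced leucine zipper gene TSC22D3 was higher (0.99). In all 10 probe sets passed, 2 up and 8 down, of which 3 carried no single gene symbol, while 796 had an unadjusted p under 0.05 against 866.35 expected by chance. The count was 1 and 2 without A-Myb arrays 1 and 2, 1 and 0 without c-Myb arrays 1 and 2, 6 (2 up and 4 down) after quantile normalization and 2 (0 up and 2 down) after scaling to a common median. G2/M genes lay higher with A-Myb: 26 of 36 had a positive change, with a median of 0.29, although none passed over all genes and 5 rose adjusted over the list alone. The camera adjusted p was 0.000169 and held without each array, with an adjusted p = 0.341 with an estimated correlation. G1/S genes were also higher (median 0.24, adjusted p 0.00672, or adjusted p = 0.341 with an estimated correlation and 0.200 without c-Myb array 1). Replication histones were lower (median -0.25, adjusted p 0.0189, or adjusted p = 0.343 with an estimated correlation, 0.236 without A-Myb array 2 and 0.175 without c-Myb array 1).

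The transactivation domain effect compares A-Myb and CHA, which carry the A-Myb transactivation domain, with c-Myb and AHC. EPHX1 was lower with the A-Myb domain by -1.69 ± 0.16 and ASS1 by -1.68 ± 0.15. Mean EPHX1 signals were 3125 ± 58.9 with c-Myb and 2772 ± 311.5 with AHC, against 973.4 ± 232.4 with A-Myb, 865.4 ± 38.3 with CHA and 681.6 ± 105.7 with GFP (SD, n = 2). ASS1 averaged 3695 ± 409.7 with c-Myb and 5106 ± 776.1 with AHC, against 1252 ± 364.4, 1484 ± 64.1 and 1102 ± 110.9 with A-Myb, CHA and GFP. The chromatin reader ZMYND8 (-1.29), the retinoic acid binding protein CRABP2 (-0.90), SFN (-0.87), DHRS2 (-0.81), ACOT7 (-0.80), the kinase anchor AKAP1 (-0.80) and isocitrate dehydrogenase IDH2 (-0.66) were lower as well. Higher with the A-Myb domain were the retinoic acid-induced receptor GPRC5A (1.09), securin PTTG1 (0.71), the sodium pump subunit ATP1B1 (0.68, with another probe set of the opposite sign) and the cyclin-dependent kinase subunit CKS1B (0.63).

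In that test 17 probe sets passed, 4 up and 13 down, and 1454 had an unadjusted p under 0.05. The count was 10 and 5 without A-Myb arrays 1 and 2, 5 without either c-Myb array, 5 and 10 without AHC arrays 1 and 2, and 30 and 8 without CHA arrays 1 and 2; ASS1, CRABP2, EPHX1 and GPRC5A passed without each of the 8. It was 14 (1 up and 13 down, or 7.14% against 23.5% up) after scaling to a common median, and 0 both with no filter and without a trend in the spread, where limma still gave 1279 with an unadjusted p under 0.05. Cell cycle genes lay higher with the A-Myb transactivation domain as a mean over both backgrounds. Of 36 G2/M genes 33 had a positive effect, with a median of 0.24; PTTG1 passed, and 7 rose and 1 fell adjusted over the list alone. CCNB2 was at 0.72, BUB1 at 0.84, UBE2C at 0.63 and CDC25B at -0.66, none passing over all genes. In the G1/S list 33 of 38 were positive, with a median of 0.28 and none passing (CDC6 0.83). The camera adjusted p was 7.25e-07 for G2/M and 1.04e-05 for G1/S, and both calls and directions held without each of 8 arrays and under both other scalings. Scaling to a common median, which moved the median of all genes from 0.02 to -0.09, lowered the list medians to 0.12 and 0.17. Each had an adjusted p = 0.192 with an estimated correlation, and fry gave 0.0364 for each.

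Smaller list shifts with the transactivation domain were less stable. Cholesterol synthesis was lower (median -0.20, adjusted p 0.0119, or adjusted p = 0.278 with an estimated correlation), and the adjusted p was 0.123 without A-Myb array 2, 0.0616 without c-Myb array 2, 0.0986 without AHC array 1 and 0.0744 without CHA array 2. Hypoxia and glycolysis genes were lower (median -0.10, adjusted p 0.0159, or adjusted p = 0.206 with an estimated correlation), and it was 0.0771 without c-Myb array 1, 0.105 without AHC array 1 and 0.0599 without CHA array 1. Ribosomal proteins had a median of 0.11 and an adjusted p of 0.0253, or adjusted p = 0.636 with an estimated correlation. After quantile normalization their median was -0.02, the direction downward and the adjusted p 0.763; after scaling to a common median these were -0.01, upward and 0.620. Without A-Myb array 2, c-Myb array 2, AHC array 1 or CHA array 2 the adjusted p was 0.529, 0.624, 0.346 or 0.345.

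The DNA binding domain effect compares A-Myb and AHC with c-Myb and CHA. TSC22D3 was higher with the A-Myb DNA binding domain by 1.08 ± 0.12: its mean signal was 4570 ± 189.6 with A-Myb and 4480 ± 737.1 with AHC, against 2300 ± 32.2 with c-Myb, 1997 ± 217.0 with CHA and 1742 ± 49.6 with GFP (SD, n = 2). TM4SF1 (2.12), the spindle checkpoint gene MAD1L1 (1.57), the hyaluronan receptor CD44 (1.08), the hypoxia-inducible factor EPAS1 (0.93), CACNG4 (0.79) and AKAP1 (0.70, with another probe set of the opposite sign) were higher too. LOXL1 of elastic fibre assembly (-1.24), KYNU (-1.09), FABP5 (-1.07), the peptidase KLK6 (-0.90), CYP1B1 (-0.89), the polyamine enzyme SAT1 (-0.86), ST6GALNAC2 (-0.75) and ATP1B1 (-0.74) were lower. Of 17327 probe sets 18 passed, 9 up and 9 down, and 1065 had an unadjusted p under 0.05. Only TSC22D3 among the 15 named genes passed without each of the 8 arrays. The count was 5 and 1 without A-Myb arrays 1 and 2, 2 and 1 without c-Myb arrays 1 and 2, 7 and 1 without AHC arrays 1 and 2, and 30 and 2 without CHA arrays 1 and 2; it was 5 (5 up and 0 down) after scaling to a common median, and 0 with no filter or without a trend in the spread, where limma gave 1022 with an unadjusted p under 0.05. Steroid and xenobiotic metabolism was lower (19 genes, median -0.19, CYP1B1 passing, 2 down adjusted over the list alone) at an adjusted p of 0.0156, or adjusted p = 0.342 with an estimated correlation. This p was 0.137 without A-Myb array 1, 0.102 without AHC array 2 and 0.0879 without CHA array 2. G2/M genes had a median of -0.05 and an adjusted p of 0.952.

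Single exchanges gave 19 probe sets for AHC against c-Myb, 4 for CHA against c-Myb, 6 for AHC against A-Myb and 1 for CHA against A-Myb. In the c-Myb background the A-Myb DNA binding domain raised TM4SF1 (3.37), MAD1L1 (2.05), CD44 (1.57), AKAP1 (1.21), the interferon-induced IFITM3 (1.04) and TSC22D3 (0.95). It lowered ELF1 (-2.38), LOXL1 (-2.17), SAT1 (-1.50), KLK6 (-1.45), the calcium pump ATP2A3 (-1.43), CYP1B1 (-1.26), MAPK3 (-1.13) and AKR1C2 (-0.97). CHA was below c-Myb in EPHX1 (-1.85), ASS1 (-1.31) and DHRS2 (-1.22). AHC was above A-Myb in ASS1 (2.05), EPHX1 (1.53), ISG20 (1.48), AKAP1 (1.45) and CRABP2 (1.16), and below it in GPRC5A (-1.79). TSC22D3 was lower with CHA than with A-Myb (-1.20). G2/M genes were lower with AHC than with A-Myb (median -0.49, 33 of 36 not positive, 1 up and 8 down adjusted over the list alone), with an adjusted p of 2.83e-12 that held without each array and an adjusted p = 0.0962 with an estimated correlation. The other exchange of the transactivation domain, CHA against c-Myb, had a G2/M median of 0.03 with 20 of 36 positive and an adjusted p of 0.422. In both exchanges of the DNA binding domain the chimera lay lower, although these exchange the domain in opposite directions. They thus do not show an effect of that domain, and the combined DNA binding domain effect above did not pass for this list. AHC against c-Myb had a median of -0.19 and an adjusted p of 0.00661, or adjusted p = 0.210 with an estimated correlation. That call was lost without AHC array 2. CHA against A-Myb had -0.21 and an adjusted p of 0.0263, or 0.149 without A-Myb array 2, 0.341 without CHA array 2, 0.119 after quantile normalization and adjusted p = 0.492 with an estimated correlation.

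The split for AHC against c-Myb was 7 up and 12 down, 9 up and 8 down after quantile normalization and 3 up and 13 down after scaling to a common median, and its count was 0 without AHC array 2 or c-Myb array 2 and 1, upward, without c-Myb array 1. CHA against c-Myb, with 4 down, gave 4 up and 0 down with no filter, 48 without CHA array 1, 2 without CHA array 2 and 1, upward, without c-Myb array 2; AHC against A-Myb gave 2 without either AHC array; CHA against A-Myb, with 1 down, gave 11 up and 2 down with no filter, 1, upward, without A-Myb array 1, 45 without CHA array 1 and 0 without CHA array 2 or A-Myb array 2. For the interaction of the domains, limma called 0 probe sets, with 1217 at an unadjusted p under 0.05 against 866.35 expected by chance, and 5 without CHA array 1. GPRC5A (1.39 ± 0.27), SAT1 (1.27), OXLD1 (3.85), SLC1A2 (-5.17), GML (-5.27), CD53 (-2.23) and CHD4 (-1.67) had the smallest p-values among named genes, each with an adjusted p of at least 0.339. Among lists the interaction was positive for G2/M genes (median 0.40, adjusted p 0.000345) and estrogen response (0.31, 0.00141) and negative for haematopoietic markers (-0.77, 0.00251), each with an adjusted p = 0.331 with an estimated correlation; the latter 2 had 0.0850 without CHA array 2. Whether the effect of exchanging a domain depends on the other was thus not detectable for single genes at this precision.

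On U95A no probe set passed for 3 of 4 comparisons in MCF-7 cells. GFP virus against uninfected cells gave 0 in limma and 11 at an unadjusted p under 0.05. Chance alone would give 569.3, and counts far below it mark an inflated spread, so they do not show that an effect was absent. The heat shock gene HSPA6 was at 2.11, the stress gene DDIT3 at 1.65 and syndecan SDC4 at -2.07. c-Myb against GFP gave 0 and 272. KRT16 was at 3.48 ± 0.95, the interferon-induced IFI27 at 3.44, the psoriasin gene S100A7 at 3.29, VCL at 2.42, involucrin IVL at -3.14 and ITGA2B at -2.91. Without GFP array 1 the GFP group rests on array 2, whose signal range was narrow (given below). The median c-Myb change of the tested probe sets then moved from -0.64 to -1.20. A-Myb against GFP gave 0 and 646, and 15 and 4 without GFP arrays 1 and 2; CTNNAL1 was at 3.68 ± 0.76, TSC22D3 at 2.63, NME3 at -4.16 and JUNB at -3.79. A-Myb against c-Myb gave 8 probe sets, each lower with A-Myb: PRSS23 (-4.97), CA12 (-4.52), MUC1 (-4.44), NME3 (-4.17), SLC25A1 (-4.07), SELENBP1 (-4.06), GFUS (-4.04) and SLC37A4 (-3.92); MUC1 had another probe set of the opposite sign. None passed without any 1 of the A-Myb or c-Myb arrays, after quantile normalization or without a trend in the spread, where 1131 and 1406 had an unadjusted p under 0.05 in limma. The arrays differed in signal range: the ratio of the 95th to the 5th percentile was 342 and 313 with c-Myb, 366 and 19.2 uninfected, 211 and 9.98 with GFP, and 63.3 and 50.1 with A-Myb. The actin 3' to 5' ratio was 3.67 and 2.61 with A-Myb against 1.504 and 0.995 with c-Myb, and that of GAPDH 1.73 and 1.85 against 1.37 and 1.16.

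**Figure D2:**
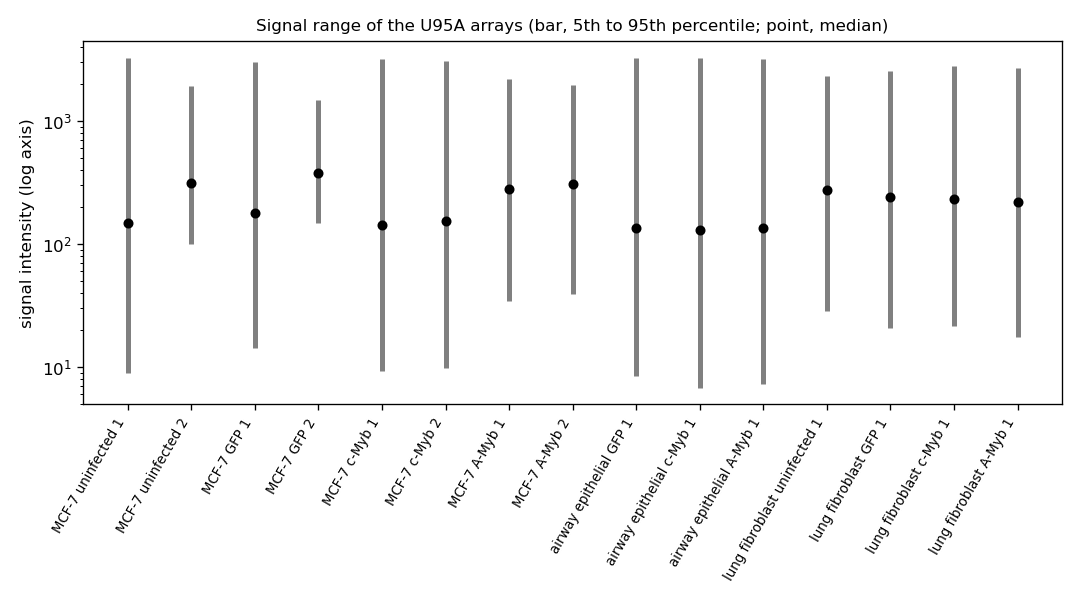
Signal intensity (log axis) of the 15 U95A arrays, with a bar from the 5th to the 95th percentile and a point at the median. MCF-7 GFP array 2 (ratio of the percentiles 9.98) and uninfected array 2 (19.2) have a narrower range than both c-Myb arrays (342 and 313).

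Genes that passed on U133A mostly had the same sign on U95A. For c-Myb this held for 67 of 85 genes (78.8%, Wilson interval 69.0 to 86.2%), and for A-Myb for 53 of 70 (75.7%, 64.5 to 84.2%), against 58.2% and 51.2% of all genes. The genes raised by c-Myb on U133A had a median of 1.13 on U95A, where all genes had -0.35. Without the narrow-range uninfected and GFP arrays 2 and both A-Myb arrays these medians were 0.55 and -0.06, and 72 of 84 genes (85.7%, 76.7 to 91.6%) had the same sign. Over all 6646 shared genes the correlation was weak, with Pearson's r of 0.227 and Spearman's rho of 0.231 for c-Myb and 0.028 and 0.035 for A-Myb. Among the genes that passed, r was 0.197 for c-Myb, or 0.382 without the narrow-range arrays, and -0.004 for A-Myb. All 70 A-Myb genes were raised on U133A, so their share counts only positive changes on U95A. The labels do not say whether both designs received the same RNA.

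In the airway epithelial cells, RRAD, a small GTPase gene, was at 8272 with c-Myb and 5485 with A-Myb against 785.4 with GFP, log2 differences of 3.40 and 2.80. The tight junction gene CLDN10 (4.23 and 3.54), the TNF receptor adaptor TRADD (3.10 and 3.25), TRIM22 (2.80 and 2.72) and ZNF318 (3.11 and 2.66) were higher with both proteins, and KHDRBS3 (2.81), MMD (3.10) and ZBTB18 (3.17) with c-Myb. CDC20, an activator of the anaphase-promoting complex (3.68), ST3GAL1 (3.02), CD83 (2.86) and CXCR4 (2.58) were higher with A-Myb. HOXC4 (-4.25), RAB35 (-2.78) and DUSP7 (-2.76) were lower with c-Myb, and NDRG2 (-2.90) and PLK1 (-2.32) with A-Myb. PTPRS was lower with both proteins, at -2.56 with each. The lower signal of CLDN10, CD83, HOXC4 and PTPRS lay below the floor of 54.5, so their differences are bounds. DHRS2 was higher by 2.12 and 1.59, TM4SF1 by 1.48 and 1.24 and TSC22D3 by 1.51 and 1.54, whereas KRT16 was at 0.00 and -0.63. The KRT16 signal was already 27032.7 on the airway GFP array, whose 95th percentile was 3261.92. Genes that c-Myb raised in MCF-7 cells on U133A were higher in 60 of 86 cases (69.8%, Wilson interval 59.4 to 78.5%), against 50.5% in random lists, with a median of 0.26 at the 99.99th percentile. Genes raised by A-Myb were higher in 56 of 76 (73.7%, 62.8 to 82.3%), with a median of 0.36. These sets were taken from U133A after the U95A counts had been seen, and both comparisons share 1 GFP array.

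In lung fibroblasts RRAD was again far higher, at 3741 with c-Myb and 1897 with A-Myb against 54.5 with GFP. CTNNAL1, which rose with each protein in MCF-7 cells, was higher by 5.71 and 5.69, but its signal on the GFP array was 41.4 against 1289.4 in uninfected cells (-4.56). The chemokine CXCL8 (4.87 and 5.83), the kinase MKNK2 (4.51 and 4.52) and CNTN2 (4.26 and 4.23) were higher with both proteins. The cell cycle inhibitor CDKN1C (4.83) was higher with c-Myb, and the heat shock genes HSPA6 (5.76) and CRYAB (4.13), and FOS (4.04), with A-Myb. ARF6 (-4.85), KLHL9 (-4.78) and RRS1 (-4.75) were lower with c-Myb and TCF21 (-4.04) with A-Myb. GFP virus against uninfected cells gave higher signals of SSR1 (5.16) and HSPA1B (4.76). DHRS2 was at -1.88 with c-Myb and 0.38 with A-Myb, TSC22D3 at 0.07 and 0.33, KRT16 at 0.19 and 0.86 and TM4SF1 at 1.03 and 1.56. IL6 was lower with A-Myb than with c-Myb by -5.83. The lower signal of RRAD, CTNNAL1, CDKN1C, FOS, SSR1, KLHL9, RRS1, TCF21 and IL6 lay at or below the floor of 54.5, so these differences are bounds. Genes raised by c-Myb in MCF-7 cells were higher in 59 of 92 (64.1%, 53.9 to 73.2%), with a median of 0.30, and those raised by A-Myb in 55 of 77 (71.4%, 60.5 to 80.3%), with a median of 0.66. The fibroblast arrays differed broadly, with an SD of log2 differences of 1.34 to 1.59 against 0.573 to 0.754 for the epithelial arrays, and the 3' to 5' signal ratio of actin, a sign of RNA quality, was 23.0 on the uninfected fibroblast array and 9.30 to 20.4 on the epithelial arrays.

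G2/M genes, many of them bound by the MuvB complex together with B-Myb, were mostly higher with A-Myb than with c-Myb in the lung cells. The actin 3' to 5' ratio moved with these comparisons: it was 20.4 with c-Myb, 10.4 with GFP and 9.30 with A-Myb in the airway cells, and 4.63, 2.20 and 1.86 in the fibroblasts. In airway epithelial cells 17 of 19 were higher with A-Myb than with GFP, with a median of 1.61: CDC20 was at 3.68, cyclin CCNB2 at 2.10, KIF11 at 2.08, and the ubiquitin-conjugating enzyme UBE2C at 2.02, while PLK1 was at -2.32. With c-Myb 7 of 11 were higher, with a median of 0.17. These sets differ, since a gene counted only if bright enough on the higher array; over the 10 genes measured in each airway comparison, 9 were higher with A-Myb (median 1.40) and 7 with c-Myb (median 0.43). In fibroblasts 6 of 29 were higher with c-Myb than with GFP (median -1.13; CDC25B -3.05, CCNB1 -2.80, FOXM1 -2.60) and 19 of 29 with A-Myb (median 0.27; CENPF 3.17). A-Myb lay above c-Myb in 25 of 29 (median 1.49; UBE2C 3.18, CCNA2 3.05, TPX2 3.04), and in 24 of the 27 measured in each fibroblast comparison. The lower signals of CCNB2 in the airway cells and of FOXM1 and CENPF in the fibroblasts lay below the floor. The airway A-Myb median and the fibroblast A-Myb against c-Myb median exceeded all random lists, and none of these lung values was tested.

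**Figure D3:**
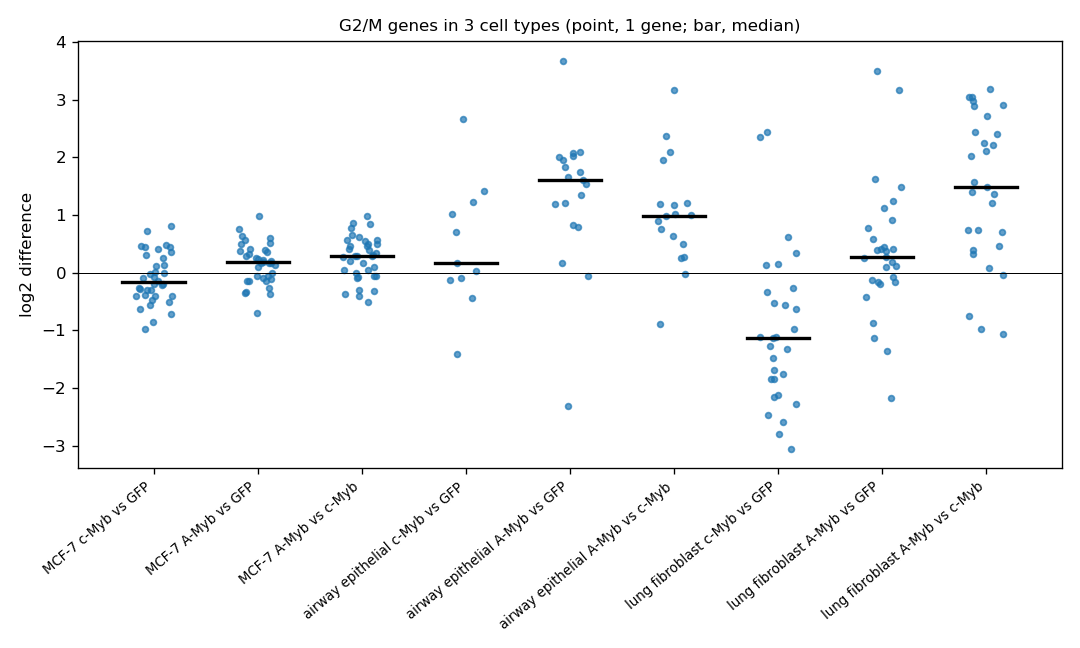
Log2 differences of G2/M genes in MCF-7 cells (U133A, 2 arrays per group), airway epithelial cells and lung fibroblasts (U95A, 1 array per group), for c-Myb and A-Myb against GFP and A-Myb against c-Myb. Each point is a gene and the bar is the median, for A-Myb against c-Myb 0.29, 0.99 and 1.49.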

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

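The 2 tests on metallothioneins and the 2 on the U95A calls were chosen only after the result was seen. In 5 cases picked out here a gene list moved in opposite directions in 2 cell types, both MCF-7 replicates moving one way and the lung array the other. Their lung medians lay at or below the 0.31th percentile of random lists. Less extreme opposite moves were also seen in airway cells. Hypoxia genes with c-Myb (-0.29) and estrogen response with A-Myb (-0.28) lay at the 0.59th percentile there, while both lists were higher in MCF-7 cells. With c-Myb against GFP in airway epithelial cells, epithelial markers had a median of -0.32, against 0.23 and 0.05 in the MCF-7 replicates. Heat shock genes were at -0.50, against 0.30 and 0.25, and immediate early genes at -0.42, against 0.05 and 0.28. Metallothioneins in lung fibroblasts were at -0.90 with c-Myb and -1.39 with A-Myb, against 1.22 and 1.77, and 1.84 and 2.29, in MCF-7 cells. On the fibroblast GFP array MT1E was already at 115734 and MT1H at 62018.6, where the 95th percentile was 2559.28. MT2A was at 755.4 and MT1G at 336 there. Of 9 genes 2 were higher with c-Myb and 1 with A-Myb, among them MT1G (1.82 and 0.54). Whether the starting level matters was not tested. The actin 3' to 5' ratio, a sign of RNA quality, was 20.4 on the airway c-Myb array against 10.4 with GFP, and 4.63 with c-Myb, 1.86 with A-Myb and 2.20 with GFP in fibroblasts. These differences were not tested, and each lung value rests on 1 array per group and another array design.

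Genes such as EPHX1 and ASS1 differed with the transactivation domain. In 2-group fits of the 8 Myb arrays, 3 of the 35 splits gave 2 probe sets, which was the highest value: the real transactivation split, the real DNA binding domain split and 1 split that follows neither. Counted for each domain with its real split included, this is 3 of 35, with a real value of 2 and a highest other of 2. Chance was thus not excluded for either value. These fits leave the effect of the other domain in the spread, so they do not test the counts of 17 and 18 from the main fit. A smaller amount of active protein from the viruses with the A-Myb transactivation domain would lower the genes raised by all 4 proteins; their median effect was 0.0321 (bootstrap interval -0.20 to 0.07). A difference in amount cannot be told apart from a domain difference. Genes entered this set only if A-Myb and CHA also raised them, so a gene that fell to its level with GFP was left out, and protein was not measured.

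Of 9 metallothionein genes 5 or 6 rose with each of the 4 proteins in MCF-7 cells. A response to infection itself would raise them with GFP virus, but the medians of GFP minus uninfected on U95A were -0.17 and -0.49. In both pairs the GFP array had the narrower signal range, with percentile ratios of 211 against 366 and 9.98 against 19.2. A narrower range can itself lower bright signals, so these medians do not decide the question. The rise was measured against cells infected with GFP virus, so infection was common to both sides. Probe sets that share sequence could spread the rise of a few members over the family. On U133A the highest number of proteins for which a specific metallothionein probe set passed was 0, but those probe sets were dim. Specific probe sets on U95A were not examined for this. How many members rose on U133A cannot be told apart from shared hybridization. A response to the Myb proteins stays open as a hypothesis.

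The 8 genes lower with A-Myb than with c-Myb on U95A had a median of -4.12 there and of -0.23 on U133A, where the lowest was NME3 at -1.13. A difference between the proteins of the size seen on U95A is not borne out by that median of -0.23. The signal range of the A-Myb arrays was compressed, with ratios of the 95th to the 5th percentile of 63.3 and 50.1 against 342 and 313. Such compression predicts a small median on U133A, but so does any cause confined to the U95A arrays. The 95th percentile was 2197 and 1964 against 3178 and 3072 with c-Myb, a much smaller difference than those of the 8 genes. Compression alone was thus not shown to cause falls of that size. A sign of RNA quality moved with the same comparison and was not tested: the actin 3' to 5' ratio was 3.67 and 2.61 with A-Myb against 1.504 and 0.995 with c-Myb.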

How the results depend on the processing

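The fit with signal range as a block, the single-array checks of lists and the choice of CHA array 2 as an array to doubt came after the results were seen; leaving out each array in turn was planned. Of the counts compared, 138 stayed within 1.5 times and 119 moved. The cause was not tested. Counts of 0 that remained 0 were tallied as having stayed. They include most settings of the domain interaction and all of GFP against uninfected cells on U95A. The tally thus does not measure how stable the counts above 0 were. In the order c-Myb, A-Myb, AHC and CHA against GFP, A-Myb against c-Myb, DNA binding domain and transactivation domain, the main counts were 158, 125, 272, 69, 10, 18 and 17. With no filter on dim probe sets they were 46, 46, 82, 40, 0, 0 and 0, and without a trend 2, 0, 6, 0, 0, 0 and 0. With only the arrays of the groups compared, c-Myb, A-Myb, AHC, CHA and A-Myb against c-Myb gave 21, 26, 148, 5 and 0. An adjusted p under 0.10 gave 258 for c-Myb, 137 for CHA, 31 for AHC against c-Myb, 17 for U95A A-Myb against c-Myb and an overlap of 60. Scaling to a common median gave 300 for c-Myb, 36 for CHA, 2 for A-Myb against c-Myb, 5 for the DNA binding domain and 7 for CHA against c-Myb. Quantile normalization gave 6 for A-Myb against c-Myb, 1 for CHA against c-Myb and 0 for CHA against A-Myb; the filter at the 60th percentile gave 2, 1 and 0, and the floor at the 5th percentile 2 for A-Myb against c-Myb. For the exchanges AHC against c-Myb, CHA against c-Myb, AHC against A-Myb and CHA against A-Myb, no trend gave 0 for each; no filter gave 0 for both AHC exchanges and 13 for CHA against A-Myb, and only their own arrays 1 for CHA against c-Myb, 3 for AHC against A-Myb and 0 for CHA against A-Myb. The 8 calls of U95A A-Myb against c-Myb became 0 under both scalings, no filter, the stricter filter, no trend, only their arrays and signal range as a block. Replicate differences correlated at -0.001 to 0.0905 over 10 pairs of U133A groups, and at -0.0484 to 0.791 over 6 pairs of U95A groups, with 1 over 0.1 (uninfected with GFP), so the numbers did not pair the arrays throughout; as a replicate block they gave 130 for CHA, 32 for AHC against c-Myb, 7 for CHA against c-Myb, 2 for CHA against A-Myb, and on U95A 13 for A-Myb against GFP and 107 for A-Myb against c-Myb. Without CHA array 2, c-Myb gave 153, A-Myb 113, AHC 275, CHA 21, A-Myb against c-Myb 2, the domains 2 and 8, and CHA against c-Myb and A-Myb 2 and 0. Leaving out single arrays, with the lone array assumed to vary like the other groups, gave 34 to 123 for c-Myb, 40 to 111 for A-Myb, 98 to 176 for AHC, 21 to 183 for CHA, 0 to 2 for A-Myb against c-Myb, 1 to 30 and 5 to 30 for the domains and 0 to 5 for their interaction. For the exchanges, in the order given, it gave 0 to 13, 1 to 48, 2 to 7 and 0 to 45; on U95A it gave 0 to 99 for c-Myb, 0 to 15 for A-Myb and 0 to 0 for A-Myb against c-Myb. The highest U95A counts for c-Myb and A-Myb against GFP came without GFP array 1, which left only the narrow-range GFP array 2. Of 336 list tests 71 passed with the preset correlation, 0 with an estimated correlation and 5 with fry. Of 144 calls of named genes, counted once per comparison, 114 passed after quantile normalization, 95 after scaling to a common median, 18 with no filter and 5 without a trend. The balance of up and down turned for some counts. CHA went from 66 up and 3 down to 67 and 116 without CHA array 1, and AHC against c-Myb from 7 and 12 to 9 and 8 after quantile normalization and 1 and 0 without c-Myb array 1. CHA against c-Myb went from 0 and 4 to 4 and 0 with no filter and 1 and 0 without c-Myb array 2, and CHA against A-Myb from 0 and 1 to 11 and 2 with no filter and 1 and 0 without A-Myb array 1. With no filter the split was 27 up and 19 down for c-Myb, 29 and 17 for A-Myb, 53 and 29 for AHC and 26 and 14 for CHA. Signal over background limits dim genes: those near the floor could not show a fall.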

Other observations

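All values in this part were chosen after the data were seen and none was tested. In lung fibroblasts, of 19 heat shock genes 17 were higher with GFP virus than in uninfected cells, with a median of 1.57, and 18 were higher with A-Myb than with GFP, with a median of 1.26; with c-Myb 14 were higher, with a median of 0.53. In airway cells the heat shock medians were -0.05 with A-Myb and -0.50 with c-Myb against GFP, and 0.26 for A-Myb against c-Myb. In the fibroblasts HSPA6 was at 23395.1 with A-Myb against 431.4 with GFP. Of 24 immediate early genes in the fibroblasts 19 were higher with A-Myb than with GFP (median 0.98), FOS by 4.04 from a signal below the floor. With c-Myb 11 of 23 were higher (median -0.11). In airway cells 6 of 19 were higher with A-Myb (median -0.30) and 6 of 20 with c-Myb (median -0.42). The uninfected fibroblast array had a 3' to 5' actin ratio of 23.0, against 2.20 for GFP, 4.63 for c-Myb and 1.86 for A-Myb.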
